A study of Papio hamadryas with 14 samples.

How the data were processed

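Total RNA from whole baboon kidney was extracted with Trizol and labelled with biotin as cRNA, per the labels. Each sample was hybridised to a human Affymetrix array. The deposited values are probe set signal intensities on a linear scale, made by the authors with GCOS, per the submitters' processing notes. The software version, signal algorithm and scaling target are not given in the sources used here. Both tables hold the same 16186 probe sets, 43 of them controls. The 2% trimmed means of the fetal arrays differed by at most 1.02 times, and those of all arrays by 1.07 times, so the deposited intensities were used without rescaling.

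Groups were taken from the labels: 60dG (2 arrays), 90dG, 125dG and 160dG (3 each) and adult (3). Gene names came from the platform annotation. Of the probe sets, 14068 have 1 gene symbol, 735 have several and 1340 besides the controls have none; those with several or none gave no gene name. For each of 9580 genes the probe set with the highest mean over the fetal arrays was used. Values were transformed as log2(signal + 16), so fold changes of dim genes are understated. Genes whose mean lay above the median of all probe sets (7.60 on the log2 scale, a signal of 178) were kept, which left 5278 genes. The effect of baboon sequence on single probes was not analysed here.

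Fetal stages were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) over all 11 fetal arrays, with Benjamini-Hochberg adjusted p under 0.05. The comparisons were a moderated F over the stages, each successive pair, 160dG against 60dG, a mid-gestation contrast, and a slope in log2 per 10 days. Of the 37 gene lists fixed before the data were examined, 32 had 5 or more tested genes and were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. The other 5 lists were too small (adrenal gland 2 tested genes, adipocyte 3, skeletal muscle 0, neural 4 and Y-linked 2) and gave no test. Adult and 160dG arrays, on different array types, were not tested gene by gene; list medians were ranked among 10000 random lists of matched level. Genes were named by a rule fixed before the data were examined: the 10 largest changes each way between 60dG and 160dG among called genes without overlap, for the trend and for that comparison; the 5 largest each way among called genes without overlap for each step and the mid-gestation contrast; the 10 largest each way for the adult comparison; up to 4 members with the steepest trend in each list; and a fixed set of kidney genes. Some fixed genes and 1 gene list are not reported here. Other list members named in the text were chosen after their values were seen. The camera counts at an unadjusted p and the list of long genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

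The model was checked on simulated data with each gene's real mean, 1 residual spread per gene shared by all arrays, and 200 changed genes among 5278. Arrays that vary more than others, or whose genes shift together, were not simulated. False calls made up 2.0% to 6.9% of the calls. It recovered 48.5% of 2-fold changes from 60dG to 90dG, 69.5% from 90dG to 125dG, 70.0% from 125dG to 160dG, 60.5% from 60dG to 160dG and 72.5% for a trend of 2-fold in all. For 4-fold changes it recovered 96.5%, 97.5%, 97.5%, 96.0% and 96.5%. camera on the linear trend recovered a shifted list of 15 genes in 20 of 20 simulations and called 0 of 620 unchanged lists; the simulated genes were not correlated, so false calls among correlated genes were not checked by it. Alternatives were another pseudocount (1 or 64), no filter or a filter at the 0.75 quantile, quantile normalization, eBayes without a trend, array weights, the replicate number as a block, all probe sets, and leaving out each array. A named gene that did not pass and stayed below the threshold was counted as keeping its call whatever its sign. Leaving out the 90dG arrays and the GAPDH covariate were added after seeing the data.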

Results

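The series profiles messenger RNA in whole kidney of the baboon (Papio hamadryas) through fetal development. Kidneys were sampled at 60 days of gestation (60dG, 2 arrays), 90dG, 125dG and 160dG (3 arrays each), and in adults of 6, 7 and 12 years (3 arrays). The labels call the fetal replicates biological, and those of the adults give an age for each. Each RNA was hybridised to a human Affymetrix expression array, so a baboon transcript that differs in sequence from its human probes can give a lower signal. The 11 fetal arrays are of 1 array type and the 3 adult arrays of another. The median probe set signal lay between 172.9 and 194.6 on the fetal arrays and between 210.2 and 214.4 on the adult arrays. Arrays carry no count depth, and their number limits the precision.

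Across the 4 fetal stages, 960 of 5278 tested genes differed (limma moderated F, adjusted p under 0.05). The steepest rise among named genes was that of CXCL14, a chemokine, whose signal went from 64.2 ± 25.7 (SD, n = 2) at 60dG to 2315 ± 1293 (SD, n = 3) at 160dG. The steepest fall was that of AFP, the fetal plasma protein alpha-fetoprotein, from 2320 ± 1101 (SD, n = 2) to 88.0 ± 29.6 (SD, n = 3). The question is which genes follow the successive stages that the design names. The count was 532 without 60dG replicate 1, 638 without 60dG replicate 2, 622 without 90dG replicate 3 and, chosen after seeing the data, 459 without the 90dG group.

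A linear trend over gestation was called for 514 genes, of which 255 rose and 259 fell (limma, adjusted p under 0.05). Values here are log2 differences between 160dG and 60dG, with the SE of the fit. Among the risers were GATM, which makes the creatine precursor guanidinoacetate (3.46 ± 0.53), AOC1, the diamine oxidase (3.53 ± 0.35), CXCL14 (4.77 ± 0.38) and PTGDS, a prostaglandin D synthase (2.81 ± 0.27). Among the fallers were HMGA2, a chromatin protein of proliferating fetal tissue (-3.76 ± 0.17), the embryonic globin HBE1 (-3.62 ± 0.36), the cartilage collagen COL2A1 (-3.48 ± 0.30), the Wnt antagonist DKK1 (-2.58 ± 0.24) and the RNA-binding protein IGF2BP3 (-2.58 ± 0.26). The naming rule required that the 60dG and 160dG arrays did not overlap, which also held for 42.8% of all tested genes (chance gives 20%). UGT2B28 also rose (4.36 ± 0.52), and its probe set, like that of PTGDS, has a name that marks possible sharing with other transcripts. The count of trends was 317 without 160dG replicate 1 and 333 without 160dG replicate 3.

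**Figure D1:**
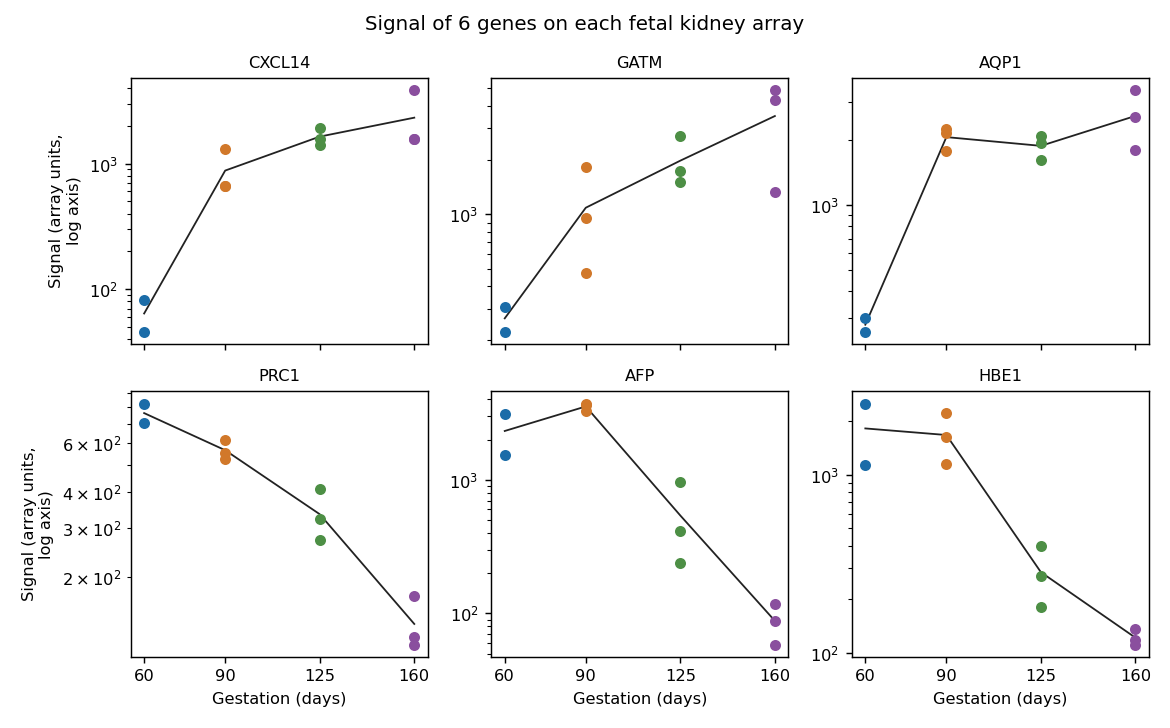
Array signal, on log axes in array units, against gestation in days for 6 genes. Points are single arrays coloured by stage and lines join the stage means; CXCL14 rises from a mean of 64.2 to 2315 and AFP falls from 2320 to 88.0.

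In the list of the proximal tubule, the segment that reabsorbs most filtered solute, the median relative to 60dG was 0.93 to 1.37 on the 90dG arrays, 1.27 to 1.39 at 125dG and 1.09 to 1.92 at 160dG on the log2 scale, so most of the change lay before 90dG. For the linear trend, 12 of 24 tested members rose (21 when adjusted over the list alone) and none fell, with camera adjusted p = 5.39e-12, and adjusted p = 0.184 with an estimated correlation. Between 60dG and 160dG, SLC22A2, an organic cation transporter, rose by 2.81 ± 0.29 and the peptidase MME by 1.66 ± 0.20. In the fatty acid oxidation list, 9 of 25 tested members rose (11 when adjusted over the list alone), with camera adjusted p = 3.79e-07, and adjusted p = 0.147 with an estimated correlation. In that list SLC27A2, a fatty acid transporter, rose by 1.85 ± 0.19 and PPARGC1A, a coactivator of mitochondrial genes, by 1.54 ± 0.31; without 60dG replicate 2 the call of PPARGC1A between these stages was lost (limma, adjusted p = 0.0881). For gluconeogenesis and amino acid metabolism, 6 of 22 tested members rose (12 when adjusted over the list alone), and PCK2 rose by 2.04 ± 0.24 (camera adjusted p = 2.19e-06, and adjusted p = 0.184 with an estimated correlation).

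The lists of the loop of Henle, podocytes, distal tubule and endothelium had fewer tested genes than that of the proximal tubule. In the loop of Henle list, 4 of 7 tested members rose (4 when adjusted over the list alone), with camera adjusted p = 4.71e-04, and adjusted p = 0.0554 with an estimated correlation. The sodium-potassium-chloride cotransporter SLC12A1 went from 566 ± 17.7 (SD, n = 2) to 1800 ± 588 (SD, n = 3), a rise of 1.60 ± 0.27, and the prostaglandin receptor PTGER3 rose by 2.16 ± 0.25. In the podocyte list, 4 of 15 tested members rose (6 when adjusted over the list alone), with camera adjusted p = 0.00162, and adjusted p = 0.0554 with an estimated correlation; the glomerular basement membrane collagen COL4A3 rose by 1.89 ± 0.33 and HTRA1 by 1.73 ± 0.22. In the distal tubule list, 1 of 5 tested members rose (4 when adjusted over the list alone), with camera adjusted p = 0.00211, and adjusted p = 0.147 with an estimated correlation. For endothelium, 0 of 12 members passed in limma, over all genes or over the list alone, and 6 had an unadjusted p under 0.05, while the set test gave camera adjusted p = 0.00308, and adjusted p = 0.166 with an estimated correlation.

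In the MHC and interferon list, 4 of 12 tested members rose (10 when adjusted over the list alone) for the trend, with camera adjusted p = 7.07e-06, and adjusted p = 0.166 with an estimated correlation. Between 60dG and 160dG, where 9 of 12 members rose (11 when adjusted over the list alone), the set also passed with the estimated correlation (adjusted p = 0.0289). HLA-DRA, a class II chain, rose by 2.76 ± 0.32, and B2M, the light chain of class I, by 1.28 ± 0.20. The complement list passed for the trend (camera adjusted p = 0.0448, and adjusted p = 0.348 with an estimated correlation), and 1 of 8 tested members rose (1 when adjusted over the list alone), namely C7. C7 differed by 2.02 ± 0.27 between 60dG and 160dG. The call of the complement and acute phase list was lost without 60dG replicate 1 (camera adjusted p = 0.253) or 2 (0.108), with no filter (0.0913) and with quantile normalization (0.0627).

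Cell cycle genes fell together. For the trend, 23 of 26 tested members fell (24 when adjusted over the list alone) and none rose (camera adjusted p = 5.20e-24; adjusted p = 0.0228 with an estimated correlation), the only list that passed with the estimated correlation for the trend. Cyclin B2 (CCNB2) fell by 2.83 ± 0.26, the spindle regulator PRC1 by 2.37 ± 0.23 and the anaphase activator CDC20 by 2.51 ± 0.36 on the log2 scale. In the nephron progenitor list, 3 of 14 tested members fell (6 when adjusted over the list alone), with camera adjusted p = 0.00669, and adjusted p = 0.147 with an estimated correlation. MYCN and EYA1, which act in progenitor growth and kidney induction, had differences of -2.44 ± 0.28 and -1.65 ± 0.24, while FGF9 of the same list rose by 0.86 ± 0.22, a call lost between these stages without 60dG replicate 1 (limma, adjusted p = 0.215) or 160dG replicate 1 (0.0783) and for the trend without 160dG replicate 1 (0.0611). In the early nephron list, 2 of 10 tested members fell (2 when adjusted over the list alone), SOX9 and HEY1, with camera adjusted p = 0.0058, and adjusted p = 0.184 with an estimated correlation. A second SOX9 probe set above the filter differed by 0.10, against -1.51 ± 0.25 for the probe set used. Among cytosolic ribosomal proteins, 5 of 27 tested members fell (6 when adjusted over the list alone), with camera adjusted p = 5.74e-06, and adjusted p = 0.311 with an estimated correlation. With quantile normalization the call of the cytosolic ribosomal proteins was lost (camera adjusted p = 0.571).

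**Figure D2:**
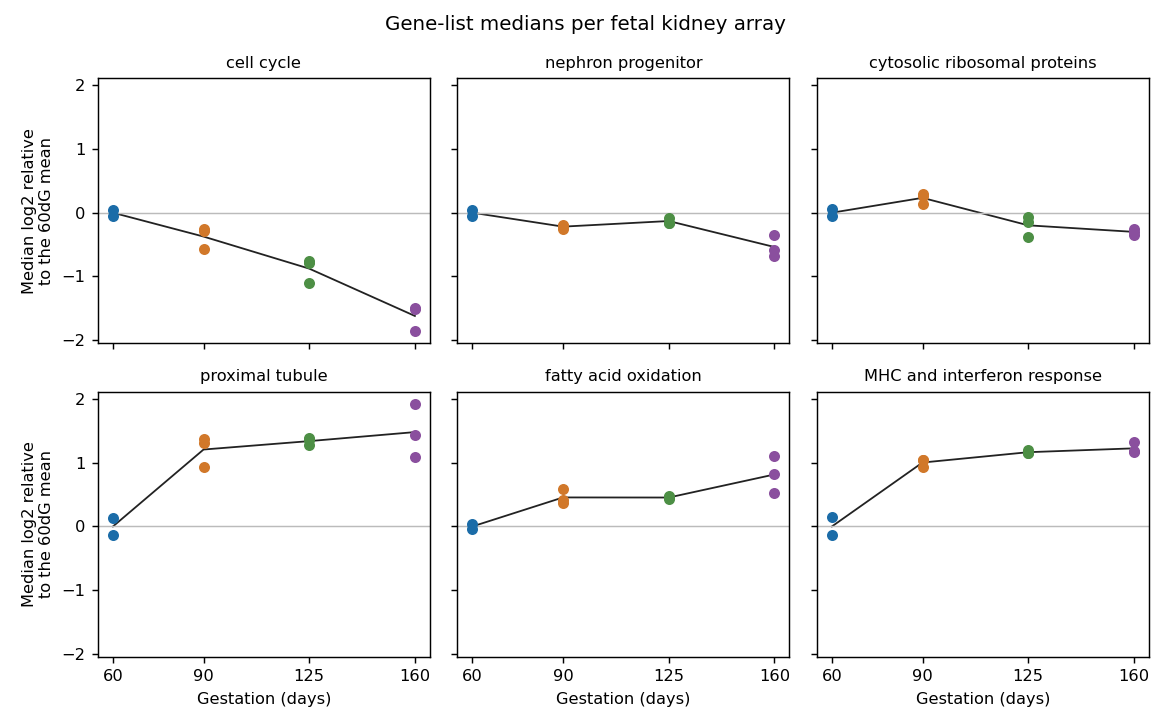
Median log2 value of 6 gene lists on each fetal array, relative to the 60dG mean of each gene, against gestation in days. Points are arrays coloured by stage and lines join the stage means; between 60dG and 160dG the median change of the cell cycle genes was -1.65 and that of the proximal tubule genes 1.55.

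The other 18 lists did not pass for the trend, with camera adjusted p in limma from 0.0566 to 0.976. In the ureteric bud list 4 of 11 members fell, among them SOX9, while the set gave camera adjusted p = 0.0716; adjusted over the list alone 4 fell and 2 rose. In the collecting duct list 2 of 8 members rose and 1 fell (4 and 2 when adjusted over the list alone); SCNN1A, a subunit of the epithelial sodium channel, rose by 0.17 ± 0.03 log2 per 10 days. In the mural and mesangial list 2 of 11 members rose, MYLK and RGS5, and 1 fell (5 and 2 when adjusted over the list alone). For the Wnt list, 4 of 25 members rose and 3 fell (5 and 4 when adjusted over the list alone). The lists of renal stroma (camera adjusted p = 0.132), matrix (0.846), oxidative phosphorylation (0.976), erythroid genes (0.862) and leukocytes (0.154) were among the 18. Of 100 regroupings of the arrays, the real one included, 20 gave 10 or more lists and 3 gave 14 or more (camera, preset correlation).

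Between the first and last fetal stage, 614 genes differed, 365 higher and 249 lower at 160dG (limma, adjusted p under 0.05), and 338 of them differed at least 2-fold. The genes with the largest rises were CXCL14, UGT2B28, PDZK1IP1 (3.57 ± 0.28), AOC1 and GATM, followed by the antioxidant enzyme GPX3 (3.30 ± 0.39), the water channel AQP1 (3.09 ± 0.23) and the esterase CES1 (2.88 ± 0.39). A second AQP1 probe set above the filter differed by 0.96 between 60dG and 160dG and by 0.41 from 60dG to 90dG. Proximal tubule members rose in 19 of 24 cases (21 when adjusted over the list alone) and cell cycle members fell in 23 of 26 (24 over the list alone). Of 32 lists, 18 passed, and with an estimated correlation 2 did, cell cycle (adjusted p = 0.0402) and MHC. Groups did not overlap for 42.8% of all tested genes, where chance gives 20%. The 60dG group has 2 arrays, and the count was 242 without replicate 1 and 366 without replicate 2, where the remaining array is assumed to vary like the other groups.

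From 60dG to 90dG, 481 genes differed, 292 higher and 189 lower (limma, adjusted p under 0.05). GPX3 rose by 3.45 ± 0.39, CXCL14 by 3.44 ± 0.38, PDZK1IP1 by 3.25 ± 0.28, UGT2B28 by 3.13 ± 0.52 and AQP1 by 2.81 ± 0.23. The paternally expressed gene PEG10 (-1.70 ± 0.31), the condensin subunit SMC4 (-1.82 ± 0.30) and the chaperones HSP90B1 (-2.12 ± 0.39) and DNAJC10 (-1.75 ± 0.31) were lower. Of the proximal tubule list, 17 of 24 members rose (19 when adjusted over the list alone), with camera adjusted p = 1.67e-15, and adjusted p = 0.193 with an estimated correlation. Of the MHC list 6 of 12 rose (9 over the list alone), with camera adjusted p = 9.76e-07, and adjusted p = 0.0634 with an estimated correlation. The macrophage and leukocyte list, whose cells also carry class II genes, passed upward with 2 of 7 members (3 over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.238 with an estimated correlation), here and between 60dG and 160dG (camera adjusted p = 0.0172, and adjusted p = 0.24 with an estimated correlation). Oxidative phosphorylation passed upward with 3 of 30 members (3 over the list alone; camera adjusted p = 0.0406, and adjusted p = 0.455 with an estimated correlation), a call lost without 60dG replicate 2 (0.0981), 90dG replicate 2 (0.0736) or 90dG replicate 3 (0.0634), with quantile normalization (0.0525) and, chosen after seeing the data, with the GAPDH control ratio as a covariate (0.113). Of the immediate early genes, which respond to stimuli and to tissue handling, 4 of 11 rose (8 over the list alone), with camera adjusted p = 5.95e-04, and adjusted p = 0.238 with an estimated correlation. In all, 14 of 32 lists passed with camera, and with an estimated correlation 0 passed and 8 had an unadjusted p under 0.05. Without 60dG replicate 1 the count of genes was 81 (68 higher and 13 lower), without 60dG replicate 2 164 (117 and 47), without 90dG replicate 2 298 (177 and 121), without 90dG replicate 3 242 (167 and 75) and, chosen after seeing the data, without both of these 94 (43 and 51). HSP90B1 was lost without 60dG replicate 1 (limma, adjusted p = 0.0649) and PEG10 without 60dG replicate 2 (adjusted p = 0.0542).

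The 90dG arrays also differ in their control probe sets. The ratio of 3' to 5' GAPDH control signal was 1.78, 2.46 and 3.43 in 90dG replicates 1, 2 and 3, and between 1.62 and 1.99 on the other fetal arrays. The geometric mean of the 9 spike-in control probe sets was 942, 1786 and 2184 on the 90dG arrays and at least 2248 on the others. The control signals thus differ in both steps at 90dG. Of the gene lists, cell cycle passed downward in both (camera adjusted p = 1.66e-04 and 8.48e-04, and adjusted p = 0.238 and 0.681 with an estimated correlation). Oxidative phosphorylation passed upward and then downward, and ribosomal proteins had camera adjusted p = 0.0652 upward and then passed downward, but no list passed in either step with an estimated correlation. With the log2 GAPDH ratio as a covariate, chosen after seeing the data, the counts were 217 genes from 60dG to 90dG and 33 from 90dG to 125dG. The ratio was raised only in 90dG replicates 2 and 3, so the covariate can also take up a difference of stage. These counts cannot tell 3' bias from stage.

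**Figure D3:**
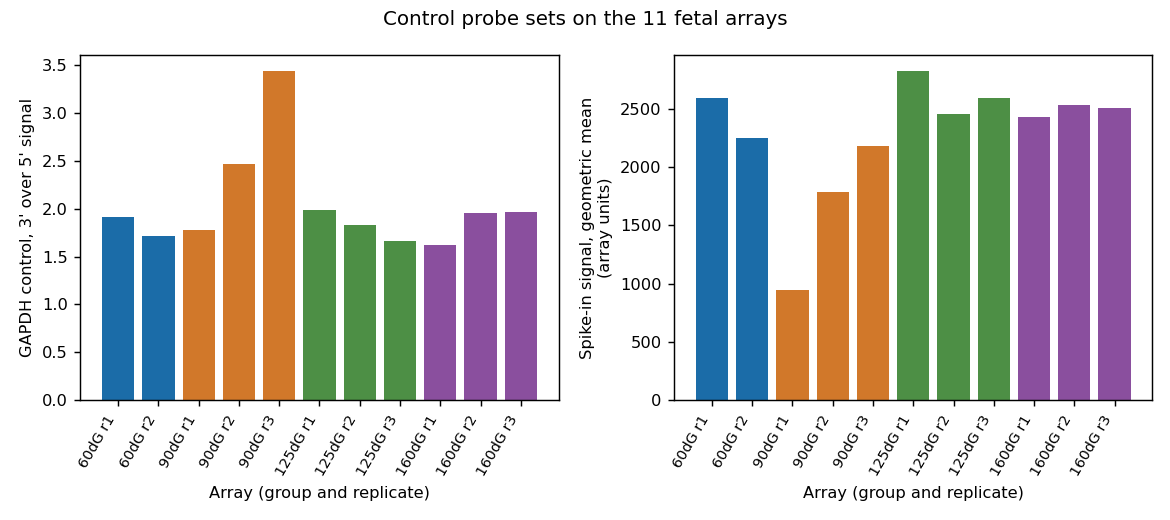
Control probe sets on each fetal array, as bars from 0 with 1 bar per array coloured by stage. The left panel gives the ratio of 3' to 5' signal of the GAPDH control, highest at 3.43 in 90dG replicate 3, and the right panel the geometric mean of the spike-in controls in array units, lowest at 942 in 90dG replicate 1.

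From 90dG to 125dG, 273 genes differed, 135 higher and 138 lower (limma, adjusted p under 0.05). AFP fell from 3541 ± 245 to 541 ± 382 (SD, n = 3 each; -2.90 ± 0.39), HBE1 differed by -2.50 ± 0.32 and HMGA2 by -1.52 ± 0.16. TIMP2, an inhibitor of metalloproteinases, was 2.12 ± 0.39 higher, the transcription factor ELF1 1.82 ± 0.35 and DNAJC10 1.66 ± 0.28. Of 32 gene lists 3 passed and were lower: ribosomal proteins (camera adjusted p = 2.27e-06, and adjusted p = 0.681 with an estimated correlation), cell cycle (camera adjusted p = 8.48e-04, and adjusted p = 0.681 with an estimated correlation) and oxidative phosphorylation (camera adjusted p = 0.00339, and adjusted p = 0.681 with an estimated correlation). Members called were 9 of 27, 4 of 26 and 1 of 30 (20, 7 and 5 when adjusted over the list alone). With quantile normalization the call of the cytosolic ribosomal proteins was lost (camera adjusted p = 0.488), and with fry 0 lists passed and 9 had an unadjusted p under 0.05. Of 114 genes called in this step and the step before, 112 had opposite signs. That count was 8 without 60dG replicate 1, 27 without 60dG replicate 2, 213 without 90dG replicate 1, 41 without 90dG replicate 2, 15 without 90dG replicate 3, 21 without 125dG replicate 1 or 3, 56 without 125dG replicate 2 and 12 with the GAPDH covariate. Both steps share the 90dG arrays, which alone gives a negative correlation. Over all genes the correlation was -0.538, against -0.447 in simulated unchanged groups, and the covariance -0.114 against -0.031. The simulation gave a gene the same spread on every array, so a wider spread of the 90dG arrays was not covered. Left-out arrays moved the count of 273 most for 125dG replicate 3 (34), 90dG replicate 3 (44), 125dG replicate 1 (63), 90dG replicate 2 (126), 125dG replicate 2 (151), the 60dG replicates (170 and 174) and 90dG replicate 1 (441). TIMP2 was lost without 90dG replicate 3 (limma, adjusted p = 0.0542) or 125dG replicate 3 (0.0699), ELF1 without 125dG replicate 1 (0.0549) or 3 (0.0623), and TIMP2, ELF1 and DNAJC10 with the GAPDH covariate.

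From 125dG to 160dG, 17 genes differed, 4 higher and 13 lower (limma, adjusted p under 0.05), and 436 had an unadjusted p under 0.05. EAPP rose by 1.66 ± 0.24, the prostaglandin receptor PTGER4 by 1.38 ± 0.18, the pericyte gene RGS5 by 1.27 ± 0.24 and the natriuretic peptide receptor NPR3 by 1.15 ± 0.22. AFP (-2.23 ± 0.39), COL2A1 (-2.03 ± 0.27), ADGRG2 (-1.71 ± 0.32), the Wnt effector LEF1 (-1.50 ± 0.28) and MYCN (-1.48 ± 0.25) fell. The cell cycle list shifted down by a median of -0.75 with 2 of 26 members called (16 when adjusted over the list alone; camera adjusted p = 5.01e-19; adjusted p = 0.122 with an estimated correlation). Of 32 lists 13 passed with camera, and with an estimated correlation 0 passed and 6 had an unadjusted p under 0.05. The count of genes was 0 in limma without 125dG replicate 1 (363 at an unadjusted p under 0.05), 2 without 160dG replicate 1, 3 without 160dG replicate 3, 7 without 125dG replicate 2 or 3, 6 without 90dG replicate 2, 10 without 90dG replicate 3 and 6 without the 90dG group. COL2A1 and PTGER4 were lost only without 125dG replicate 1 (adjusted p = 0.0624 and 0.0624), EAPP also without 160dG replicate 1 or 3, and each of the other 6 genes without at least 5 arrays in turn.

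The mid-gestation contrast, the mean of 90dG and 125dG against that of 60dG and 160dG, was called for 49 genes, 38 higher and 11 lower in mid-gestation (limma, adjusted p under 0.05). The stage with the highest mean was 90dG or 125dG in 30 of the 38 and 160dG in 8, and the lowest mean lay at 90dG or 125dG in all 11. Of the 49, 47 were also called from 60dG to 90dG, 11 from 90dG to 125dG and 3 from 125dG to 160dG. The 8 include AQP1 (1.20 ± 0.15), named after its values were seen, with mean signals of 279.5, 2063, 1879 and 2586 at the 4 stages; its second probe set had a contrast of -0.06. LHFPL6 (1.06 ± 0.13), the imprinted gene MAGEL2 (0.94 ± 0.17), the adhesion receptor ADGRA2 (0.83 ± 0.14) and the elastin cross-linking enzyme LOXL1 (0.73 ± 0.12) had maxima with no overlap between the groups. EAPP (-1.36 ± 0.18), NPR3 (-1.15 ± 0.17), the splicing factor PRPF39 (-0.86 ± 0.14) and the scaffold AKAP9 (-0.79 ± 0.14) had minima. The count was 14 without 60dG replicate 1, 27 without 60dG replicate 2 or without 125dG replicate 2, 146 (83 higher and 63 lower) without 90dG replicate 1, 32 without 90dG replicate 2, 28 without 90dG replicate 3, 31 without 125dG replicate 1 and, chosen after seeing the data, 12 (6 and 6) without 90dG replicates 2 and 3. MAGEL2, PRPF39 and AKAP9 were lost without 60dG replicate 1 (limma, adjusted p = 0.0576, 0.0576 and 0.088), and MAGEL2, ADGRA2 and LOXL1 without 60dG replicate 2 (0.0667, 0.0672 and 0.0552). Of 32 lists 7 passed with camera, all upward, and with an estimated correlation 0 passed and 3 had an unadjusted p under 0.05.

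Among kidney genes fixed in advance, LRP2 (megalin, the endocytic receptor of the proximal tubule) differed by 1.56 ± 0.35 between 160dG and 60dG, the phosphate transporter SLC34A1 by 1.15 ± 0.22, TOP2A by -2.03 ± 0.39, MKI67 by -1.05 ± 0.28 and PAX2 by -0.66 ± 0.20. Without 60dG replicate 1 each of these 5 calls was lost (limma, adjusted p = 0.11 for LRP2, 0.0647 for SLC34A1, 0.0638 for TOP2A, 0.0966 for MKI67 and 0.357 for PAX2). MKI67 was also lost without 60dG replicate 2 or 160dG replicate 3, and PAX2 without any fetal array except 90dG replicate 1; a second PAX2 probe set above the filter differed by -0.03. WT1 (-0.36 ± 0.32), NPHS1 (0.06 ± 0.38), PODXL (-0.53 ± 0.29), AQP2 (0.20 ± 0.24) and AGTR2 (0.04 ± 0.29) did not pass. SIX2, CITED1 and SLC12A3 lay below the filter and were not tested. The SIX2 signal was 237 ± 34.2 at 60dG (SD, n = 2) and 72.8 ± 49.1 at 160dG (SD, n = 3), CITED1 ranged from 174 to 201 and from 12.8 to 58.9 over the same arrays, and SLC12A3 from 91.0 to 136 and from 149 to 254. UMOD, IGF2 and H19 were not analysed here.

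Probe sets of the same gene were compared where a gene had several above the filter. Of 1349 such genes, 0 had a probe set past the threshold upward and another downward (limma), and 1, HNRNPD, had opposite trends at an unadjusted p under 0.05. In 73 genes at least 2 probe sets passed, and in all 73 they had the same direction. HNRNPD encodes an RNA-binding protein of AU-rich elements. Its probe sets had trends of -0.04, -0.03, -0.02 and 0.10 log2 per 10 days, and those of -0.03 and -0.02 did not reach the unadjusted threshold.

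Adult kidneys were set beside 160dG, the last fetal stage. By the size rule (a difference of at least 2 on the log2 scale with no overlap), 123 of 5283 genes differed, 45 higher and 78 lower in adults. The largest rises were those of metallothioneins, metal-binding proteins: MT1HL1 (5.43 ± 0.54), MT1X (5.27 ± 0.36) and MT1H (5.09 ± 0.39, SE from the replicates). MT1X had a signal of 609 ± 233 at 160dG and 23023 ± 3054 in adults (SD, n = 3 each). The metallothionein MT2A, which ranked below UPB1, had 630.4 ± 221 and 11951 ± 562. These probe sets can share signal among metallothionein genes. UPB1, an enzyme of pyrimidine breakdown, was 4.75 ± 0.25 higher, the phosphate and urate transporter SLC17A3 3.82 ± 0.09 and the retinol carrier RBP4 3.80 ± 0.56 (SE from the replicates). Lower were the collagen chaperone SERPINH1 (-4.60 ± 0.17), LTBP4 (-4.42 ± 0.27), COL1A1 (-4.09 ± 0.51), TNC (-3.87 ± 0.59), MEST (-3.61 ± 0.27), SOX4 (-3.49 ± 0.18) and elastin, ELN (-3.45 ± 0.33).

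By list, the median difference between adult and 160dG was -2.01 for renal stroma, with 9 of 18 members lower by the rule, and -1.76 for matrix, with 13 of 29; both medians lay below all 10000 random lists of matched level. It was 1.04 for the proximal tubule, with 5 of 31 members higher, and 1.03 for gluconeogenesis and amino acid metabolism, both above all random lists. The imprinted growth network had -0.94, with MEST, PEG10, DLK1, CDKN1C and PLAGL1 lower by the rule. Single genes were not tested, since every adult is on 1 array type and every fetal sample on the other, so array type and age cannot be told apart. The random lists only rank a list among genes of its level, and array type can act on that rank too. Adult and 160dG arrays did not overlap for 53.7% of genes, where chance gives 10%, and the median difference over all genes was 0.0014. With no filter the rule named 318 genes.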

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

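The tests of 3' bias and of other groupings of the arrays were chosen before their results were seen; those of long transcripts, spike-ins, liver tissue, red cells and second probe sets were chosen after related values had been seen. Groups of 2 or 3 arrays are too small for a test of single outlying arrays. Signals outside the comparisons stood out in 3 cases. The ratio of 3' to 5' signal in 90dG replicate 3 was 3.43 for the GAPDH control and 3.03 for the actin control, above every array of the other fetal stages. XIST, the transcript of the inactive X chromosome, had a signal of 4589 in 60dG replicate 1 and at most 138.7 on the other fetal arrays, while the Y-linked RPS4Y1 was 90.2 there and at least 3332 on the other fetal arrays. By these transcripts 60dG replicate 1 has a female pattern and the other fetal arrays a male one, though the labels give no fetal sex. It is the only such fetal array, and the comparisons with 60dG did not take this into account.

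As a group mean, 90dG stood apart from both neighbouring stages, but its 3 arrays were not a tight group. Over all probe sets, 90dG replicate 1 had Spearman correlations of 0.896 and 0.883 with 90dG replicates 2 and 3. With 125dG replicates 1, 2 and 3 it had 0.898, 0.904 and 0.887. Genes displaced in 90dG replicates 2 and 3, chosen against 60dG replicate 1 and 125dG replicate 1 (127 genes), were displaced in replicate 1, set against the other 60dG and 125dG arrays, by 0.370 of the displacement in replicates 2 and 3, and 99 of 127 lay in the same direction. This ratio falls between the bounds set in advance, so 3' bias of replicates 2 and 3 can be neither excluded nor named as the source. Replicates 2 and 3 also served to choose the genes, which can raise their displacement and lower the ratio. The 58 tested genes of very long coding sequence had a median of -0.15 against the neighbouring stages, and 35 of them were lower. That median lay at the 0.06 percentile of random lists, which do not keep the correlation among listed genes. The median of the long genes goes with a loss of long transcripts, though not in every long gene. The ribosomal protein genes, which are short, had a median of 0.317. Relative to 60dG their median was 0.296, 0.138 and 0.265 in 90dG replicates 1, 2 and 3. This order does not follow the GAPDH ratios of 1.78, 2.46 and 3.43, so the ribosomal values do not bear out 3' bias. All 3 of the 90dG arrays had a lower geometric mean of the spike-ins than every other fetal array. For 90dG replicate 3 the gap was small (2184 against 2248 in 60dG replicate 2). Its signal for the middle bioB spike-in (499.9) was above those of 60dG replicate 2 (449.5) and 125dG replicate 3 (478.7). A batch of the 90dG arrays cannot be told apart from the stage, since each covers the same 3 arrays. A change of the kidney at this stage also stays open, untested.

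AFP and HBE1 fell from 60dG to 160dG. Fewer red cells in the later samples stay open, since only 4 members of the erythroid list besides the globins were tested, too few to decide. From 60dG to 160dG these 4 differed by a median of 0.107 (-0.33 to 0.20) and HBE1 by -3.62. HBB was 1.08 ± 0.22 higher at 160dG (limma, adjusted p = 0.00573), and 0.88 higher without 60dG replicate 2 (adjusted p = 0.0833), but a switch between globins along gestation could raise it too. Liver tissue in the early samples stays open. Of 13 liver markers only 2, ALB and SERPINA1, lay above the filter at 60dG, too few to decide, and human probes for the other 11 need not detect the baboon transcripts. From 60dG to 160dG the AFP probe set fell by 4.45, that of ALB by 2.01 (from a mean signal of 259 to 51.4) and that of SERPINA1, which kidney can also express, by 0.435. At 90dG the AFP signal was 3541 (0.69 ± 0.44 against 60dG; limma, adjusted p = 0.344) and that of ALB 75.1, and the 13 markers lay above 160dG by a median of 0.239 (SD 0.474), where AFP lay above by 5.13; these values go against liver tissue but rest mostly on probe sets below the filter. The rules for both were changed after these values had been seen: one on HBB had counted against fewer red cells, and one on the median fall of all 13 markers (0.432) against liver tissue. A change of the kidney with stage may add to either and was not tested.

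Genes differed between adult and 160dG by the size rule. A difference between single probes of the array types would leave a second probe set of the same gene free to go either way. The second probe set took the same direction in 41 of 45 genes, 91.1% (exact 95% interval 78.8% to 97.5%). This argues against single probes as the whole cause, but the interval treats the genes as independent. They include related genes such as MT1X, MT1F and MT1E. The median size was 2.68 for the first probe set and 1.55, in its direction, for the second, so a probe-specific part stays open. The share among genes outside the rule was not computed. A general difference between the array types cannot be told apart from age, since 53.7% of genes did not overlap and each array type holds 1 age class.

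Other groupings of the arrays test whether chance can give as many calls. Among 100 regroupings of the 11 fetal arrays, only the real one (1 of 100) gave as many genes across stages (960, highest other 46). The same held for a trend (514, highest other 3) and for the mid-gestation contrast (49, highest other 32). Every regrouping mixes the stages, so real stage differences add to its spread. The counts argue against arrays that do not differ by stage at all. They cannot tell whether the mid-gestation calls exceed what other stage differences give. For gene lists along the trend, 3 of 100, the real one included, gave 14 or more, a share under 0.05, but the highest other also gave 14 and 20 of 100 gave 10 or more. For 125dG against 90dG and 160dG against 125dG there are 10 splits of 6 arrays, too few for a share under 0.05; the real split (1 in each case) gave 273 and 17 genes and the highest other 0 and 0.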

How the results depend on the processing

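The settings without 90dG arrays and with the GAPDH covariate were chosen after seeing the data. The covariate overlaps with the 90dG stage, so a lower count with it need not come from 3' bias. No list and no gene named by the fixed rule changed direction, where called, under any setting that was run; the other called genes were compared by count only. Of 7445 values of named genes, 6796 kept their side of the threshold, 508 lost their call and 141 gained one. Of 2976 values of lists, 2753 kept their side, 145 lost their call and 78 gained one. Of 180 values of adult genes 7 moved beyond the spread, 6 of them with a pseudocount of 64. For 90dG against 60dG (481 genes) the count was 94 without 90dG replicates 2 and 3 together, 217 with the covariate and 81 to 581 when single arrays were left out. For 125dG against 90dG (273) it was 171 with no filter, 155 without the intensity trend, 481 with array weights, 546 over all probe sets, 32 without 90dG replicates 2 and 3, 33 with the covariate and 34 to 441 over left-out arrays. For 160dG against 125dG (17) it was 6 with the upper-quartile filter, 7 without the intensity trend, 6 without the 90dG group, 6 without its replicates 2 and 3 and 0 to 21 over left-out arrays. For the mid-gestation contrast (49) it was 129 with array weights, 12 without 90dG replicates 2 and 3, 20 with the covariate and 14 to 146 over left-out arrays. Leaving out single arrays gave 242 to 700 for 160dG against 60dG, 317 to 504 for the trend and 532 to 1067 across stages, which fell to 459 without the 90dG group and 547 without its replicates 2 and 3. The share of higher genes ran from 45.7% to 84.0% for 90dG against 60dG (60.7% as reported), 41.3% to 75.0% for 125dG against 90dG (49.5%), 53.1% to 68.6% for 160dG against 60dG (59.4%) and 41.4% to 58.6% for the trend (49.6%); in mid-gestation (77.6%) it was 85.7% without 60dG replicate 1 and 6 of 12 genes without 90dG replicates 2 and 3, and for 160dG against 125dG (23.5%) 0 of 6 with the upper-quartile filter and 1 of 2 without 160dG replicate 1. The adult comparison gave 318 genes with no filter, where more genes enter. Genes with opposite signs in both steps at 90dG (112) numbered 19 without 90dG replicates 2 and 3, 12 with the covariate, 48 with no filter, 56 without the intensity trend, 193 with array weights, 66 with the replicate block, 210 over all probe sets and 8 to 213 over left-out arrays. The causes were not tested, except that fewer arrays enter when some are left out.

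With an estimated correlation 1 list passed for the trend (14), 0 for 90dG against 60dG (14), 0 for 125dG against 90dG (3), 0 for 160dG against 125dG (13) and 2 for 160dG against 60dG (18). With fry 21 passed for the trend, 15 for 90dG against 60dG and 21 for 160dG against 60dG. For 125dG against 90dG 0 passed with fry, and for 160dG against 125dG 2 did. With the covariate 9 passed for 90dG against 60dG, and left-out arrays gave 7 to 13 for 160dG against 125dG. With quantile normalization the share of higher lists was 33.3% against 0% for 125dG against 90dG and 72.7% against 61.5% for 160dG against 125dG.

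The replicate numbers do not pair the arrays: over 15 same-numbered pairs the correlation of deviations ran from -0.114 to 0.179, and 2 exceeded 0.1. With the replicate number as a replicate block the counts were 794 across stages, 339, 198 and 5 for the successive steps, 523 for 160dG against 60dG, 415 for the trend and 23 for mid-gestation. Dim genes, near the filter at a signal of 178, call for caution, though their certainty was not measured against that of brighter genes.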

Other observations

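Wnt pathway members moved in both directions between 60dG and 160dG. The secreted antagonist SFRP1 rose by 1.97 ± 0.30, while the antagonist DKK1 (-2.58 ± 0.24), the receptor FZD2 (-1.65 ± 0.29) and the transcription factor LEF1 (-1.94 ± 0.31) fell. Among stress proteins the small heat shock protein CRYAB rose by 2.06 ± 0.18 and the chaperone HSPH1 had a difference of -1.33 ± 0.23. FOXD1, a transcription factor of the renal stroma, had a difference of -1.27 ± 0.23. These log2 differences with SE are from limma at adjusted p under 0.05, and none of these calls between the 2 stages was lost when any single fetal array was left out.

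That adult levels extend the change seen by 125dG was a hypothesis set before its result was seen, but the rule for reading its test was changed after the value had been seen. A trend fitted to the 8 arrays of 60dG, 90dG and 125dG, which shares no array with the adult comparison, called 56 genes measured in both. Of these, 30, or 53.6%, differed between adult and 160dG in the same direction (exact 95% interval 39.7% to 67.0%, over genes that are not independent), and the share over all 4790 genes was 53.0%. As first written, an interval that reaches an even split counted against the hypothesis. As read now, the same interval leaves it undecided, since it also reaches shares well above an even split. By either reading the hypothesis gained nothing from the data, and array type also differs between adult and 160dG.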
